A study of Oryzias latipes with 6 samples.

How the data were processed

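Axial tissue of Japanese medaka (Oryzias latipes) was profiled by RNA sequencing on the Ion Torrent PGM. The labels give 6 libraries, 3 from fish exposed as embryos to the solvent DMSO and 3 from fish exposed to TCDD, the dioxin that binds the aryl hydrocarbon receptor (AHR). Per the labels' protocols, polyA RNA came from 2 µg of total RNA with an RNA integrity number of at least 9.9, and each RNA sample pooled 15 to 25 fish.

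The submitters' processing notes name Bowtie2 2.2.6 and DESeq2, with no role for either. The 1 table used here has the header of a Cuffdiff gene test, per the file headers, so which program gave its values is not settled. The genome build and annotation are not given in the sources used here; genes carry Ensembl medaka identifiers. Per the file headers, the authors deposited 1 expression value per gene and group, a test statistic, a p-value and a q-value. The deposited group values were read as FPKM (fragments scaled by gene length and library size), the unit of that layout, because they are not whole numbers and sum to 1315189 in DMSO and 1108805 in TCDD. How the authors combined the 3 libraries of a group is not given in the sources used here. The test statistic is the authors' deposited score. The p-values were all whole multiples of 5e-05 (tolerance 0.001 of a step), and 157 genes of the authors' deposited table share that smallest value. The q-values equalled Benjamini-Hochberg values recomputed over the 3286 tested genes to within 5.11e-07.

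The authors' deposited table holds 20459 genes, of which 16959 (82.9%) have a name. It marks 3286 (16.1%) as tested, 17172 as not tested and 1 as having too little data. The tested genes had a median mean FPKM of 52.6 and a lowest of 13.7, whereas 2743 untested genes lay at or above that lowest mean. Because there is no value per library, no test across samples was run, no SD or interval is given, and the depth per sample is unknown. The authors' own test is therefore the main result, as provided for before the data were examined. Genes past q 0.05 are called changed. How that test treated the 3 libraries of a group is not given, and nothing in the labels says whether the pools came from separate clutches, so p-values may measure technical spread alone.

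The log2 fold change of TCDD over DMSO was recomputed from the group values, since 993 cells of that column were unreadable. Of 15005 readable cells, 1 differed by more than 0.001. No pseudocount was added; genes listed at 0 in 1 group have no fold change and are named as listed at 0. The TCDD values summed to less than the DMSO values, and scaling both groups to equal totals would add 0.25 to every log2 fold change. The median log2 fold change of the tested genes was 0.05 as deposited. The smallest absolute log2 fold change of a called gene was 0.80, so no called gene changed direction under that scaling.

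Before the data were examined, 26 gene lists were written for AHR targets, the tissues of the dissection, tissues that could be carried over and general processes. Genes were matched to them by symbol, without regard to case and without the copy suffix that some symbols carry. The lists have 661 members in the table, of which 236 were tested, counting a gene once for each list that holds it. The 18 lists with at least 5 tested members were compared with the other tested genes by limma's cameraPR (limma 3.58.1, R 4.3.3) on the authors' statistic, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The test used the 3262 genes with a finite statistic. The median log2 fold change of each list was also placed among those of 10000 random lists of the same size, drawn from 10 bins of mean expression. Calls within a list are counted over all genes tested and again adjusted over the list alone.

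Named genes followed a rule set before the data were examined. It took called genes with a name and a mean of at least 10, the 8 with the largest rise and the 8 with the largest fall, up to 3 members of each list with the smallest q, and every CYP1 gene. The minimum was set for normalized counts and applied to FPKM. Genes listed at 0 in 1 group were kept apart from the 8 largest. The rule named 85 genes. Other genes in the text were chosen after their values were seen. Coordinates are as in the table. A further table of gene names shared no identifier with these data and was not used here.

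The list test was tested on simulated data for this comparison, with 100 simulated tables of 3262 genes and 18 lists, 3 of them shifted by 2 robust SDs. It recovered 98.7% of the shifted lists and called 0.733% of the others. The simulated genes were drawn independently from a normal distribution, with 200 of them moved at random and no correlation within a list. These rates therefore do not cover lists of genes that vary together. Nor do they cover extreme values such as the largest finite statistic of the authors' deposited table, 63.4. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives tried were other q thresholds, a minimum fold change, recomputed and Bonferroni adjustment, filters on mean FPKM, other correlations, ranks, lists without their leading member, equal totals, and other ways to treat genes at 0. The last of these, including a normal score of the authors' p, the filter at a mean FPKM of 50, the equal totals and the gene families by symbol stem were chosen after seeing the data.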

Results

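The study asked how a brief embryonic exposure to TCDD alters gene expression in the axial skeleton and its surrounding tissue in larvae. Medaka embryos of the orange-red Hd-dR strain were held for 1 h, from about 4 hours post fertilization, in 0.3 nM TCDD or in 0.1% DMSO. At 20 days post fertilization the vertebrae with adjoining muscle, fat and dermis were dissected free of head and viscera. There were 3 pooled libraries per group. The authors' deposited table gives 1 FPKM value per gene and group, so replicate errors and depth per library cannot be stated, and significance rests on the authors' own q-values.

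TCDD-exposed fish still had strongly raised AHR target genes at 20 days post fertilization. In the authors' deposited table cyp1a, the monooxygenase used as the classical marker of AHR activity, rose from 27.7 to 3258 FPKM (118-fold, q = 0.00105). This gene lies on chromosome 3 at 30530519 to 30533663, on a build that is not given in the sources used here. Matrix and muscle genes went the other way: in the authors' deposited table col1a2, a chain of type I collagen, fell from 1510 to 302 FPKM, and mylpfa, a fast-muscle myosin light chain, from 12477 to 3299 FPKM (both q = 0.00105). Of the 3286 genes tested in the authors' deposited table, 597 passed q 0.05, with 352 higher and 245 lower in TCDD.

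**Figure D1:**
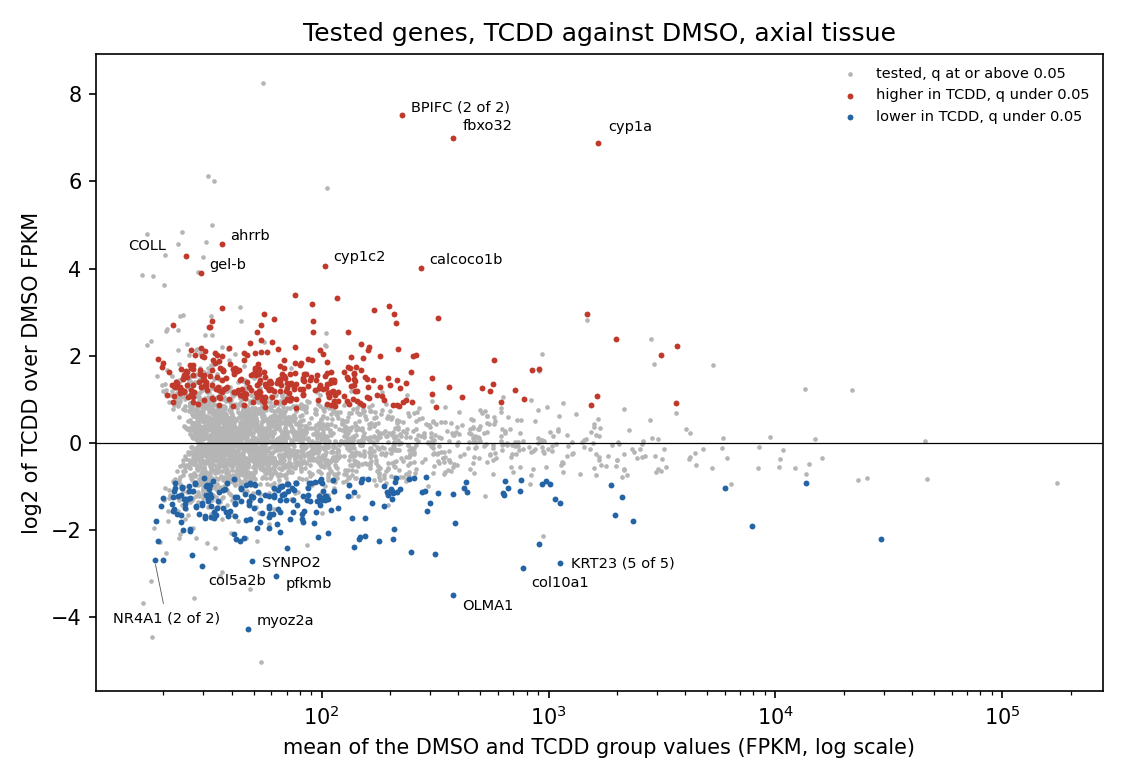
Log2 of TCDD over DMSO FPKM against the mean of both group values (FPKM, log axis) for the tested genes of the authors' deposited table that are above 0 in both groups. Each point is a gene, red or blue where it is higher or lower past q 0.05, and the 8 largest rises and 8 largest falls of called genes with a name are labelled, with BPIFC (2 of 2) at 7.52 and myoz2a at -4.28.

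The AHR battery rose as a group. In the authors' deposited table, 6 of its 7 tested members rose and 0 fell, and 7 rose when adjusted over the list alone. Besides cyp1a, the authors' deposited table has the AHR repressor ahrrb rising from 2.95 to 69.9 FPKM (q = 0.0018), cyp1c2 from 11.6 to 194 FPKM and the receptor ahr2 (2 of 2) from 31.9 to 105 FPKM (both q = 0.00105). The glucuronosyltransferase gene ugt1a7 rose from 58.2 to 266 FPKM and the ADP-ribosyltransferase gene tiparp from 27.4 to 84.1 FPKM in the authors' deposited table (q = 0.00105 and 0.0018). CYP1B, whose symbol was not on the list, was listed at 0 in DMSO and at 73.8 FPKM in TCDD in the authors' deposited table (q = 0.00105). The untested cyp1d1 had 2.94 and 6.61 FPKM in the authors' deposited table. The median log2 fold change of the list was 2.19 (limma cameraPR on the authors' statistic, adjusted p = 4.49e-08). It stood at percentile 100 of the expression-matched random lists. Of the NRF2 and oxidative stress list, 1 of 9 tested members rose in the authors' deposited table, and 1 when adjusted over the list alone. That member was catalase, cat, from 15.1 to 34.3 FPKM in the authors' deposited table (q = 0.0258), and the list did not pass (limma cameraPR adjusted p = 0.361).

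The largest rises among named genes above 0 in both groups lay partly outside the AHR battery. In the authors' deposited table fbxo32, which encodes the muscle ubiquitin ligase subunit atrogin-1, rose from 5.86 to 748 FPKM and BPIFC (2 of 2) from 2.46 to 451 FPKM (both q = 0.0209). The autophagy-related gene calcoco1b rose from 32.1 to 515 FPKM (q = 0.00105), COLL from 2.48 to 48.1 (q = 0.023) and gel-b from 3.71 to 55.2 (q = 0.00249) in the authors' deposited table. The locus of gel-b overlaps adora1 and dclre1b in the authors' deposited table, so its reads are uncertain. Called genes listed at 0 in DMSO in the authors' deposited table were also lsm7 (128 FPKM in TCDD), zgc:193616 (94.3), si:ch211-194m7.5 (51.4) and si:ch211-194m7.8 (49.8), each with q = 0.00105. Among called genes with a name and above 0 in both groups, the largest fall in the authors' deposited table was that of myoz2a, a Z-disc protein of muscle, from 90.2 to 4.63 FPKM (log2 -4.28, q = 0.0166). OLMA1 fell from 698 to 61.9 FPKM, the muscle phosphofructokinase gene pfkmb from 112 to 13.4 FPKM and SYNPO2 from 85.2 to 12.9 FPKM in the authors' deposited table (each q = 0.00105). The keratin gene KRT23 (5 of 5) fell from 1967 to 288 FPKM (q = 0.00105), at a locus shared with an unnamed gene, and the nuclear receptor gene NR4A1 (2 of 2) from 31.8 to 4.88 FPKM (q = 0.0201) in the authors' deposited table.

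Bone, cartilage and connective tissue matrix genes fell in part, and most of those that fell were collagens. In the authors' deposited table, 7 of the 24 tested non-collagen members of the osteoblast, cartilage and fibroblast lists fell and 1 rose. That split was made after the falls were seen. Of 11 tested osteoblast and bone matrix genes in the authors' deposited table, 5 fell and 0 rose (6 fell and 1 rose when adjusted over the list alone). Those 5 included col10a1, made by bone-forming cells in fish, from 1363 to 185 FPKM, col1a1b from 419 to 73.8 FPKM and SPARC from 884 to 384 FPKM in the authors' deposited table (each q = 0.00105). The osteoblast transcription factor sp7 fell from 34.4 to 5.34 FPKM (q = 0.0411), whereas the alkaline phosphatase gene alpl had 32.8 and 36.0 FPKM (q = 0.817) in the authors' deposited table. In the cartilage and notochord list 6 of 10 tested members of the authors' deposited table fell and 0 rose, and 7 fell when adjusted over the list alone. They included col11a2, from 66.2 to 15.6 FPKM, the matrilin gene matn3a, from 112 to 33.2 FPKM, and a COL2A1A row from 147 to 58.9 FPKM in the authors' deposited table (each q = 0.00105). The chondrocyte transcription factor sox9b fell from 46.6 to 14.6 FPKM in the authors' deposited table (q = 0.0053). COL2A1A stands in the authors' deposited table as separate genes under 1 symbol, and reads could be split between them. Of 18 tested fibroblast and tendon matrix genes in the authors' deposited table, 10 fell and 1 rose (10 and 2 when adjusted over the list alone). Among these, col5a2b fell from 52.0 to 7.29 FPKM, the periostin gene postnb from 332 to 83.6 FPKM and col5a1 from 123 to 49.1 FPKM in the authors' deposited table (each q = 0.00105). The fibulin gene fbln1 rose from 12.9 to 31.9 FPKM (q = 0.022), and lum had 218 and 184 FPKM (q = 0.581) in the authors' deposited table. Median log2 fold changes were -1.20 for osteoblast, -1.34 for cartilage and -0.94 for fibroblast genes (limma cameraPR adjusted p = 0.00765, 0.00852 and 0.00765).

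Muscle genes fell in part. Of 30 tested fast skeletal muscle genes in the authors' deposited table, 9 fell and 0 rose, and 12 fell when adjusted over the list alone. The parvalbumin gene pvalb4 fell from 48170 to 10465 FPKM and the troponin gene TNNI2 (3 of 5) from 3647 to 1052 FPKM in the authors' deposited table (both q = 0.00105). Other copies did not pass there: TNNI2 (4 of 5) had 2581 and 1704 FPKM (q = 0.16) and the more abundant TNNI2 (5 of 5) 29759 and 16451 FPKM (q = 0.0542). The muscle phosphoglycerate mutase gene pgam2 fell from 541 to 92.6 FPKM in the authors' deposited table (q = 0.00105). The creatine kinase genes ckma (14434 and 15386 FPKM, q = 0.876) and ckmb (44944 and 46478 FPKM, q = 0.927) did not pass in the authors' deposited table. The most abundant transcript, pvalb1, had 228225 FPKM in DMSO and 119442 FPKM in TCDD (q = 0.0915) in the authors' deposited table, or 17.4% and 10.8% of the group totals. Of 9 tested slow and cardiac-type muscle genes in the authors' deposited table, 3 fell and 0 rose (4 fell when adjusted over the list alone). They were the troponin gene tnni1d, from 152 to 61.6 FPKM, and the tropomyosin genes tpm2, from 1020 to 472 FPKM, and TPM3, from 269 to 154 FPKM, in the authors' deposited table (q = 0.00316, 0.00373 and 0.0427). Of 8 tested myogenesis genes in the authors' deposited table, 5 fell and 1 rose, and the same counts held when adjusted over the list alone. The myosin chaperone gene unc45b fell from 125 to 42.2 FPKM, smyd1b from 71.5 to 20.8 FPKM and hsp90aa1.1 from 277 to 101 FPKM in the authors' deposited table (each q = 0.00105). The smyd1b locus overlaps fabp1b.1. The desmin gene desma rose from 2524 to 4766 FPKM in the authors' deposited table (q = 0.0273). Median log2 fold changes were -0.73, -0.80 and -1.14 for fast muscle, slow muscle and myogenesis (limma cameraPR adjusted p = 8.57e-06, 0.0371 and 0.0378). The slow muscle and myogenesis calls ended at an inter-gene correlation of 0.05 (adjusted p = 0.0748 for both) and without their leading member (adjusted p = 0.0731 and 0.112).

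Immune genes rose. Of 6 tested leukocyte and immune genes in the authors' deposited table, 4 rose and 0 fell (5 rose when adjusted over the list alone). The cytokine gene il1b rose from 36.8 to 303 FPKM, the interferon regulatory factor irf1b from 17.8 to 163 FPKM and the pan-leukocyte phosphatase ptprc from 7.85 to 29.9 FPKM in the authors' deposited table (each q = 0.00105). The signalling factor stat3 also rose, from 34.0 to 65.5 FPKM (q = 0.0265), whereas mpx (2 of 2), a granulocyte enzyme, had 32.7 and 32.2 FPKM (q = 0.968) in the authors' deposited table. The median log2 fold change of the list was 1.44 (limma cameraPR adjusted p = 0.0135), a call that ended without its leading member (adjusted p = 0.135).

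**Figure D2:**
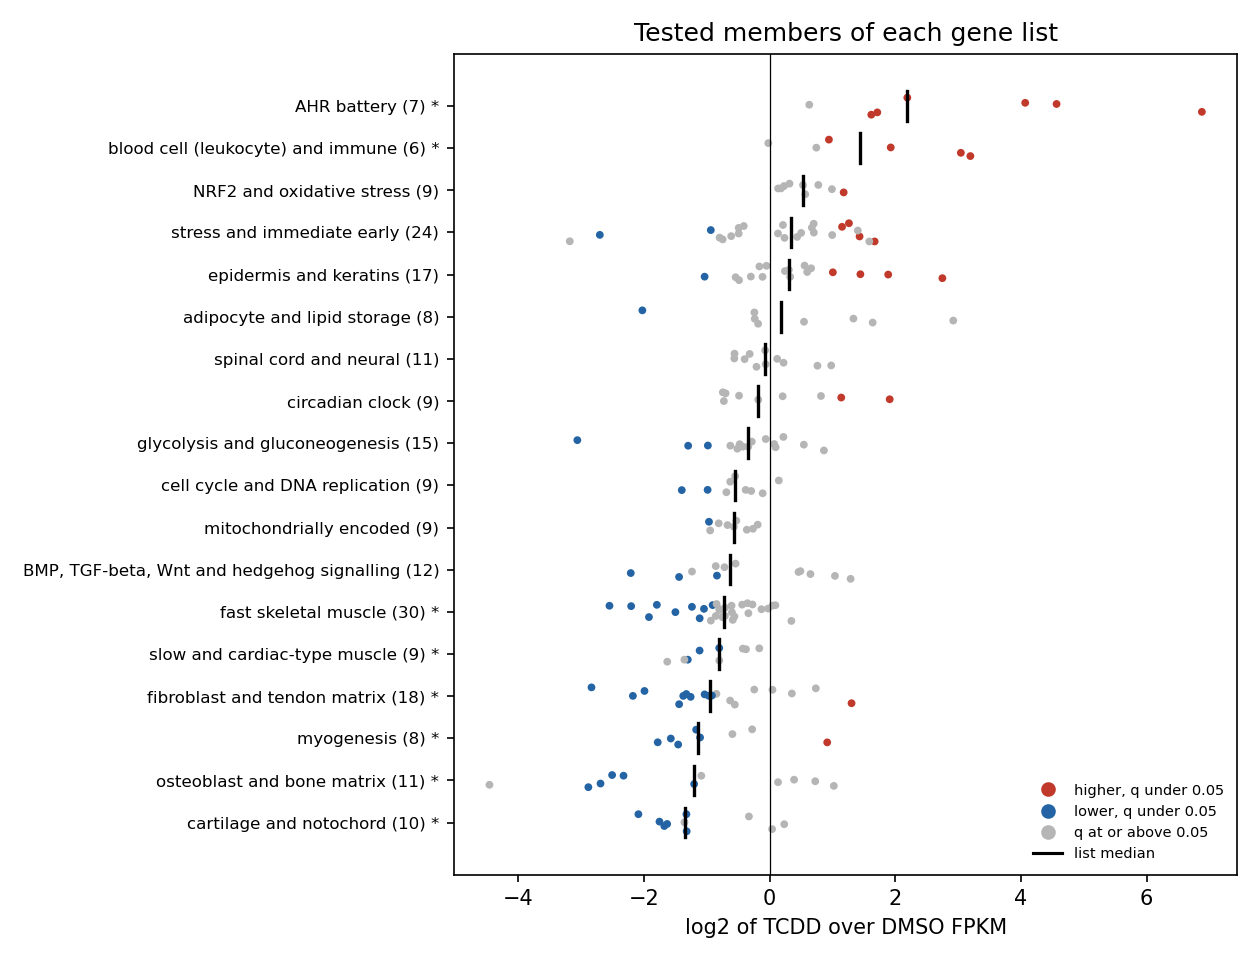
Log2 of TCDD over DMSO FPKM (x axis) of each tested member (point) of the 18 gene lists tested, with the number of tested members in parentheses and the list median as a black bar, from the authors' deposited table. A star marks an adjusted p under 0.05 by limma cameraPR; medians run from 2.19 for the AHR battery to -1.34 for cartilage and notochord.

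The other 10 tested lists did not pass, though single members did. Of 12 signalling genes (BMP, TGF-beta, Wnt and hedgehog) in the authors' deposited table, 3 fell and 0 rose (5 fell and 2 rose when adjusted over the list alone). They were the Wnt antagonist sfrp2, from 340 to 73.6 FPKM, dkk3b, from 69.5 to 25.6 FPKM, and id1, from 312 to 175 FPKM, in the authors' deposited table (q = 0.00105, 0.0373 and 0.0444). In the epidermis list 4 of 17 tested genes of the authors' deposited table rose and 1 fell, as when adjusted over the list alone. The claudin genes cldne and cldni rose from 55.2 to 371 FPKM (q = 0.00105) and from 50.5 to 137 FPKM (q = 0.0114), while the keratin gene krt5 fell from 8037 to 3926 FPKM (q = 0.034) in the authors' deposited table. Of 15 glycolysis genes in the authors' deposited table, 3 fell and 0 rose (3 when adjusted over the list alone): pfkmb, the aldolase gene aldoaa (1508 to 614 FPKM, q = 0.00105) and the hexokinase gene hk1 (1 of 2) (42.6 to 21.6 FPKM, q = 0.0213). Of 24 stress and immediate early genes in the authors' deposited table, 4 rose and 2 fell (6 and 3 when adjusted over the list alone), ddit3 rising from 61.1 to 165 FPKM (q = 0.0081). Of 9 clock genes in the authors' deposited table, 2 rose and 0 fell (3 rose and 2 fell when adjusted over the list alone), the nuclear receptor gene nr1d4b from 19.1 to 71.7 FPKM (q = 0.00105) and CRY1 (2 of 3) from 32.0 to 70.5 FPKM (q = 0.0101). The clock list had a median of -0.18 but a mean statistic above that of other genes. Of 9 cell cycle genes in the authors' deposited table, 2 fell and 0 rose (2 when adjusted over the list alone), the replication helicase genes mcm2 (60.3 to 22.9 FPKM, q = 0.00249) and mcm4 (34.6 to 17.5 FPKM, q = 0.0434). In the adipocyte list 1 of 8 genes of the authors' deposited table fell (0 when adjusted over the list alone), gpd1b from 42.0 to 10.3 FPKM (q = 0.0384). Of 9 mitochondrially encoded genes in the authors' deposited table, 1 fell (1 when adjusted over the list alone), ND5 from 2492 to 1277 FPKM (q = 0.0226), whose locus overlaps ND6. None of the 11 spinal cord and neural genes passed in the authors' deposited table (0 when adjusted over the list alone). The limma cameraPR adjusted p was 0.222 for signalling, 0.243 for epidermis, 0.169 for glycolysis, 0.85 for stress, 0.908 for the clock, 0.2 for cell cycle, 0.908 for adipocytes, 0.169 for mitochondrially encoded genes and 0.777 for neural genes.

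The remaining 8 lists, among them the tissues that could be carried over, had under 5 tested members and no list test. In the authors' deposited table, 1 of 2 tested gut and pancreas genes rose (1 when adjusted over the list alone), the intestinal cadherin gene cdh17, from 21.7 to 44.1 FPKM (q = 0.0213). Neither of 2 liver genes passed in the authors' deposited table (0 when adjusted over the list alone), apoa1b having 21.4 and 42.2 FPKM (q = 0.223). In the erythroid list 1 of 3 genes of the authors' deposited table fell (1 when adjusted over the list alone), ank1 from 240 to 91.9 FPKM (q = 0.0372), at a locus shared with an unnamed gene. The osteoclast protease gene ctsk had 70.8 and 126 FPKM (q = 0.0558) in the authors' deposited table, and 0 of 2 osteoclast genes passed (1 rose when adjusted over the list alone). Of 2 pigment cell genes in the authors' deposited table, 0 passed (1 fell when adjusted over the list alone), and 0 of 3 retinoid genes (0 when adjusted over the list alone), crabp2b having 49.4 and 28.8 FPKM (q = 0.339). No gene of the cholesterol list or of the eye and brain list was tested, so carry-over of eye and brain stays open. Among untested genes, the crystallin genes crygn2 and cryba1b were higher in DMSO, as given below.

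The smallest p the authors' test gave, 5e-05, fixed the smallest Bonferroni-adjusted p at 0.164, so no gene could pass that adjustment. Every list call ended when genes listed at 0 in 1 group were kept at the largest finite statistic, a setting chosen after seeing the data (adjusted p = 0.683 for the AHR battery), and those for cartilage, fibroblasts, slow muscle and myogenesis also ended at a mean FPKM of at least 50 (adjusted p = 0.177, 0.153, 0.177 and 0.177).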

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

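The authors' deposited table holds FPKM values for 421 list members that were not tested, each counted once however many lists hold it, and none of these enter the comparison. Those with at least 20 FPKM in TCDD and at least 4 times the DMSO value were singled out, a limit chosen after seeing the data. There were 9. The macrophage and granulocyte transcription factor SPI1 was listed at 0 in DMSO and at 43.1 FPKM in TCDD in the authors' deposited table. From the same blood cell list, mpx (1 of 2) had 4.80 and 20.8 FPKM in the authors' deposited table. The NRF2 target genes HMOX1 (1 of 2) and sqstm1 had 6.31 and 28.9 FPKM, and 6.82 and 33.3 FPKM, in the authors' deposited table. The liver secretory genes apoa2 (3.12 and 37.3 FPKM), tfa (3.36 and 21.0 FPKM) and kng1 (5.02 and 20.5 FPKM) met the same limit in the authors' deposited table, and the tfa locus overlaps an unnamed gene. The ribonucleotide reductase gene RRM2 (1 of 2) had 4.38 and 29.5 FPKM, and nfil3-5 had 4.75 and 20.1 FPKM, in the authors' deposited table. The mirrored limit, higher in DMSO, was met by 6 genes of the authors' deposited table, among them the osteocalcin gene bglap, at 49.5 FPKM in DMSO and listed at 0 in TCDD. The others, with their FPKM in DMSO, were the crystallin genes crygn2 (25.3) and cryba1b (25.3), tpx2 (24.8), plp1b (26.5) and ND2 (27.3). None of these differences has a test, and read counts are not given. The loci of SPI1 (chromosome 23, 17478479 to 17478767) and bglap (chromosome 1, 14895924 to 14896314) are far shorter than the median tested locus (5996 bp). Because FPKM is scaled by gene length, few reads on such loci can give values of this size.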

How the results depend on the processing

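No paired analysis was possible because the table has 1 value per group and no value per library. For that reason leaving out libraries, other splits of the samples and an estimated inter-gene correlation could not be run, and depth is unknown. Of 597 calls (352 higher, 245 lower), 300 (184 and 116) passed q 0.01 and 0 (0 and 0) passed Bonferroni adjustment, which the smallest p precludes; 1070 genes had an unadjusted p under 0.05. Over the 1723 genes with a mean FPKM of at least 50, a limit chosen after seeing the data, 376 passed (223 and 153), with fewer genes tested. All other settings for these counts stayed within 1.5 times. A minimum mean of 10 removed no gene and says nothing. The recomputed adjustment returned the authors' q-values and equal totals reused them, so neither could move the counts. The 8 list calls became 5 without each list's leading member, with slow muscle at adjusted p = 0.0731, myogenesis at 0.112 and leukocytes at 0.135. A correlation of 0.05 ended slow muscle and myogenesis (both 0.0748). Ranks added cell cycle (0.0284) and mitochondrially encoded genes (0.0121). The remaining settings were chosen after seeing the data. A mean FPKM of at least 50 left 3 lists, ending cartilage (0.177), fibroblast (0.153), slow muscle (0.177) and myogenesis (0.177), with fewer members tested; the leukocyte list had under 5 members left and no test. A normal score of the authors' p over all tested genes, added after the outcome of the next setting was seen, called 10 lists, adding cell cycle and mitochondrially encoded genes (both 0.0337). Keeping the 24 tested genes at 0 in 1 group at the largest finite statistic, 63.4, called 0 lists. The gene with that statistic had an authors' p-value of 0.142. AHR then had 0.683, fast muscle 0.718, and osteoblast, cartilage, fibroblast, slow muscle, myogenesis and leukocytes 0.879 each. Those values widen the spread that every list is set against. Only the clock list, not called in any setting, turned direction, downward by ranks and without its leading member. Equal totals turn the medians of the clock list (-0.18 to 0.07) and neural list (-0.07 to 0.18), neither of them called.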

Other observations

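Gene families were grouped by symbol stem, and all tests below were chosen after the results were seen. Protein breakdown genes were higher in TCDD. In the authors' deposited table, 15 of 27 tested proteasome genes rose and 0 fell (18 and 1 when adjusted over the family alone). The family had a median log2 fold change of 0.90 (limma cameraPR adjusted p = 0.000698). Among the proteasome genes, psma8 rose from 242 to 901 FPKM, psmd7 from 69.8 to 192 FPKM and the activator gene psme4a from 8.73 to 54.7 FPKM in the authors' deposited table (each q = 0.00105). Of 7 cathepsin genes in the authors' deposited table, lysosomal proteases, 6 rose and 0 fell (7 and 0 when adjusted over the family alone). CTSL rose from 405 to 1283 FPKM and ctsd from 62.7 to 164 FPKM in the authors' deposited table (both q = 0.00105). The cathepsin median log2 was 1.64 (limma cameraPR adjusted p = 0.000698). Ubiquitin, its conjugating and removing enzymes and F-box genes gave 9 rises and 0 falls among 28 in the authors' deposited table (limma cameraPR adjusted p = 0.0142), ubc rising from 1311 to 6085 FPKM (q = 0.00373). Adjusted over the family alone, 10 rose and 0 fell. That last family lost its call at a correlation of 0.05 (adjusted p = 0.0817) and at a mean FPKM of at least 50 (0.0536). Without its leading member it stood just under the limit (adjusted p = 0.0497).

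Nuclear-encoded respiratory chain and ATP synthase genes were lower, with 8 of 53 falling and 0 rising in the authors' deposited table (median log2 -0.54, limma cameraPR adjusted p = 0.000205). Adjusted over the family alone, 8 fell and 0 rose. The ATP synthase gene atp5c1 fell from 288 to 118 FPKM in the authors' deposited table (q = 0.00105). Mitochondrial ribosomal protein genes had 3 falls among 28 in the authors' deposited table (2 when adjusted over the family alone). The family did not pass in the main setting (limma cameraPR adjusted p = 0.0936). It passed by ranks (adjusted p = 0.00935) and by the normal score of the authors' p (adjusted p = 0.015), with up to 0.737 in the other settings. Cytosolic ribosomal protein genes had 1 fall among 70 in the authors' deposited table (0 when adjusted over the family alone). Their median log2 was -0.06, which becomes 0.19 at equal totals (limma cameraPR adjusted p = 0.635). Collagens had 18 falls and 0 rises among 23 in the authors' deposited table (19 and 0 when adjusted over the family alone). Their median log2 was -1.32 (limma cameraPR adjusted p = 3.47e-08). Of these 23, 15 are also members of the osteoblast, cartilage and fibroblast lists, so this result is not separate from theirs. With genes at 0 kept at the largest finite statistic the collagens had 0.263, the ubiquitin family 0.536, and the proteasome, cathepsin and respiratory chain families 0.385.

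A bias against long loci is argued against for the collagens: log2 fold change hardly followed locus length across tested genes (rho = -0.02). The collagens lie at longer loci (median 27652 bp, against 5996 bp for tested genes). Subtracting the median log2 fold change of each of 20 length bins moved the collagen median only from -1.32 to -1.30. The collagen median stood at percentile 0 of 10000 random lists matched on locus length. The collagens were grouped after their falls were seen, so that percentile decides nothing. Locus length was genomic span, and transcript length was not examined. A smaller share of bone, cartilage and fibroblast cells stays open: 7 of the 24 other members of those lists fell too, sox9b and sp7 included. The 15 collagens of the lists had a mean log2 of -1.63 (SD 0.83 across genes) and the 24 others -0.70 (SD 1.31), but the collagens were set apart after their falls were seen, so this difference decides nothing. Lower transcription per cell in TCDD-exposed fish is a candidate explanation that these values cannot separate from such a change in share.

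For the proteasome and cathepsin genes, a scaling offset was weighed with the ribosomal protein genes, since a uniform offset would move all families alike. The ribosomal protein genes lay 0.99 lower on the log2 scale than the proteasome genes, which argues against such an offset for the proteasome genes. The two-sided permutation p across genes was 2e-05, the smallest that 100000 resamples can give. The proteasome family was chosen after its rise was seen, so that p is no independent support. The cathepsins were not compared in this way. Liver, gut and pancreas carried over stay open: their list genes were higher in sum by 0.0498 of the rise of both families, but without the abundant rbp4 that sum was 158 FPKM in DMSO and 347 FPKM in TCDD in the authors' deposited table, and the level of either in these organs is not measured here. More leukocytes stay open for the proteasome genes: the mean FPKM of ptprc, lcp1, coro1a and mpx was higher by 0.151 of the mean rise of a proteasome gene, but the level of either in a leukocyte is not measured here, and the leukocyte list rose. For the cathepsins they stay open too, since 2 of those 4 genes were at least 1.5 times higher and the 3 macrophage markers of the list found, SPI1 among them, were not tested. A wider FOXO and atrophy programme is a biological hypothesis that fbxo32 could point to. Of 14 tested genes on a list of such genes, 4 rose and 0 fell in the authors' deposited table. Adjusted over the list alone, 5 rose and 0 fell, and the median log2 was 0.51. The list did not pass (limma cameraPR across genes, n = 14 tested list genes, p = 0.139). A wider programme therefore cannot be told apart from a narrower change.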
